A study of Mus musculus with 48 samples.

How the data were processed

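RNA from mouse knee joints was measured on the nCounter system of NanoString, with its version 2 inflammation panel for mouse, which counts fluorescent barcodes hybridised to single RNA molecules without amplification. Per the labels' protocols, equal masses of synovial tissue and of articular cartilage with subchondral bone were stored in a stabilising solution and homogenised, and total RNA was purified on columns. The series holds 48 samples in 4 groups of 12. Groups were taken from the sample titles and treatment labels. Nothing in the labels says whether the 12 samples of a group came from 12 animals, so p-values measure the spread between these samples, which may in part be technical.

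The values deposited by the authors are whole-number counts per probe, with no normalization or background subtraction recorded in the sources used here. The control probes were still present among the 268 probes, which include 248 endogenous genes, 6 housekeeping genes, 6 positive controls and 8 negative controls. No value was 0, and 142 values were 1, so a count of 1 may stand for an undetected molecule. Of the gene probes, 248 matched a current mouse symbol and 6 matched a synonym in the RefSeq gene table of GRCm38.p6, which was used for names only. No probe for Mmp13 was among those analysed here, so the level of the gene the siRNA targets could not be checked. The total gene count per sample ran from 36415 to 302377. The mean of the negative controls was 5.63 to 8.47 counts per group, with a highest single value of 26, so genes just above the filter lie close to background. A sample lay above the negative controls for a gene when its count exceeded their mean plus 2 SD in the same lane. By this rule, set after the data were seen, 12 genes were above them in at most 6 of 12 samples of a group. For those named, a fold against that group is given as a bound where one could be formed. For a bound, that group's values were raised to the limit where they lay below it, while the adjusted p is that of the fit to the counts. For Nos2 no bound could be formed, so its fitted values near background are given.

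Each sample was scaled by the geometric mean of Cltc, Gapdh, Gusb, Hprt, Pgk1 and Tubb5. A lane-wide positive-control factor cancels in this scaling, so adding one gives identical values. Endogenous genes with over 20 counts in at least 12 samples were tested, which left 196 of 248. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, fitted to the counts of all 4 groups at once, with contrasts between group means. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 were called. Log2 fold changes are those of the fit. Their standard errors (SE) were computed from log2(normalized count + 1) of the 12 samples in each group. Gene lists were tested with the directional p of fry in limma 3.58.1, adjusted over the 17 lists within a comparison. Fry asks whether the members of a list move, on balance, one way, and does not compare a list with other genes.

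The tests, the gene lists, the rule for genes named in the text and all alternatives not marked below as added were chosen before the data were examined. For the effect of loading and for siMMP13 against siNEG and against no treatment, the rule takes up to 12 called genes with the largest log2 fold change in each direction. For the other comparisons it takes up to 5 in each direction. It adds Mmp3, Mmp9, Il1b, Tnf, Il6, Nos2, Ptgs2, Il1rn and Arg1 in the first group of comparisons, and 2 to 4 members with the smallest p of each gene list described. A gene that this rule would name is not reported here.

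Whether siMMP13 moved the genes altered by loading was tested on a score. For every sample, log2(normalized count + 1) was averaged over the genes called in loaded untreated against healthy joints, with the sign of the loading change. The plan was to choose those genes on the healthy and untreated samples only, but the calls used came from the fit of all 4 groups, so the siMMP13 and siNEG samples entered its count filter and its estimate of the spread. The score was therefore also computed, after the data were seen, over the 99 genes called when the filter and the fit used the healthy and untreated samples alone, 85 of which were among the 91. The group difference was tested with a two-sided permutation test of the 24 labels (100000 resamples), with a 95% bootstrap interval from 10000 resamples.

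The alternatives were TMM scaling, DESeq2 size factors, total-count scaling, leaving out each housekeeping gene, no filter, a minimum of 50 counts, subtraction of the negative control mean, the Wald test of DESeq2 1.42.0, limma with a pseudocount of 1 or 10, fits of only the groups compared, the replicate number as a block, array weights, and leaving out each sample in turn. Added after the data were seen were log2 Myl2 as a covariate, leaving out 4 libraries with a divergent housekeeping profile, and fry under total-count scaling and DESeq2 size factors. The loading score without those libraries was computed over the same genes and over the genes called anew. For comparison, siMMP13 against siNEG was also refitted without each of the 84 sets of 3 other siMMP13 libraries, together with the divergent healthy library. A library's profile was called divergent when its distance from the median profile of the 6 genes lay over 3 median absolute deviations above the median distance.

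The count test was checked on simulated data drawn from the means, spreads and depths of these samples, each gene independently of the others. The check therefore does not cover shifts that many genes of a sample share. Among 196 genes simulated for loaded untreated against healthy joints, 75% of 20 genes changed 1.5-fold were recovered, as were 100% of 20 genes changed 2-fold and 100% of 20 changed 4-fold, with 1 false call among 136 unchanged genes. No pair of samples agreed within counting noise (lowest chi-square per degree of freedom 4.90). Values were plotted with matplotlib.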

Results

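Expression of inflammation genes was measured in knee joints of male C57BL/6 mice, labelled as 3 months of age. Healthy joints (n = 12) were compared with joints subjected to repeated compressive loading, a noninvasive model of post-traumatic osteoarthritis. From 8 weeks of age, loaded knees received 500 cycles at 9 N, 5 times per week for 4 weeks. Loaded joints were left untreated (n = 12) or were treated with nanoparticles that carry small interfering RNA (siRNA) and an antibody to type II collagen, a main protein of cartilage. The siRNA was a negative control (siNEG, n = 12) or was directed against Mmp13, which encodes a collagen-degrading metalloproteinase (siMMP13, n = 12). Median total gene counts per sample were 113747 in healthy, 162624 in loaded untreated, 116985 in siNEG and 148381 in siMMP13 joints, with a full range of 36415 to 302377. Mmp13 itself was not among the genes analysed here, so knockdown was not measured. Of 248 endogenous genes, 196 passed the count filter.

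The first comparison addressed the effect of loading, in untreated loaded against healthy joints. Ccl2 and Ccl7, which encode monocyte-attracting chemokines, had the largest fitted increases among the genes called. Ccl2 was 10.2-fold higher (log2 fold change 3.35 ± 0.57 SE, adjusted p = 6.2e-06) and Ccl7 was 7.44-fold higher (2.89 ± 0.47), each in 12 of 12 loaded samples relative to the healthy median. Interferon-induced genes rose together, with Ifit3 at 1854 ± 636 normalized counts (SD, n = 12) against 395 ± 410 in healthy joints. Mmp3, which encodes a matrix-degrading metalloproteinase, rose from 352 ± 501 to 1762 ± 803 normalized counts (SD, n = 12; log2 fold change 2.32 ± 0.56 SE), whereas Retnla, a marker of alternatively activated macrophages, was at least 5.58-fold lower, a bound because only 6 of 12 untreated samples lay above the negative controls (adjusted p = 8.8e-07). In total 91 genes differed by edgeR's quasi-likelihood test, 62 higher and 29 lower.

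Of the 18 interferon response genes, 15 rose, none fell and 3 did not pass (16 rose when adjusted over the list alone), and the list rose as a whole (fry, adjusted p = 2.0e-06, median log2 fold change 1.62). Ifi44 rose by 2.26 ± 0.33, Ifit1 by 2.06 ± 0.38, Oas2 by 1.98 ± 0.24, Oas1a by 1.81 ± 0.22 and Stat2, a transcription factor of interferon signalling, by 0.90 ± 0.12. Of 13 CC chemokines and receptors, 8 rose and 2 fell, the same numbers as when adjusted over the list alone (fry, adjusted p = 0.00011). Ccl5, a T-cell chemoattractant, rose by 2.04 ± 0.29 and Ccl21a by 1.77 ± 0.32, and the eosinophil receptor Ccr3 had a log2 fold change of -0.76 ± 0.15. Of 8 CXC chemokines and receptors, 4 rose and 1 fell, also when adjusted over the list alone (fry, adjusted p = 0.0041). Cxcl10 rose by 2.07 ± 0.40, Cxcl9 by 1.19 ± 0.24 and Cxcl5 by 1.12 ± 0.26, while Cxcr4 was lower (-0.53 ± 0.12).

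Both measured metalloproteinases passed, in opposite directions. Mmp9, which neutrophils carry, was lower in loaded joints (-0.51 ± 0.19, adjusted p = 0.029, 11 of 12 samples), a call lost without Gusb in the scaling, and fry placed the pair higher on balance (adjusted p = 0.0066). Ptgs2, the inducible cyclooxygenase, rose at least 2.41-fold, to 46.8 ± 23.2 normalized counts (SD, n = 12; adjusted p = 2.1e-07) from 8.52 ± 3.62 in healthy joints, where 2 of 12 samples lay above the negative controls. The stress-induced chaperone gene Hspb1 rose by 2.62 ± 0.43 and Hif1a, the oxygen-sensing transcription factor, by 1.10 ± 0.13. Arg1, which like Retnla stands on the macrophage and monocyte list, was at least 3.51-fold higher, with 6 of 12 healthy samples above the negative controls. Of 12 oxidative and endoplasmic reticulum stress genes, 3 rose and 2 fell (the same when adjusted over the list alone), and the list did not pass (fry, adjusted p = 0.35). Of 15 eicosanoid genes, 3 rose and 3 fell (3 and 2 when adjusted over the list alone; fry, adjusted p = 0.62), with a median log2 fold change of -0.11 and a mean of 0.12. Besides Ptgs2, the leukotriene receptor gene Cysltr1 rose by 1.27 ± 0.22 and the prostaglandin receptor gene Ptgfr by 0.89 ± 0.15, while Alox15, a lipoxygenase of eosinophils and macrophages, had a log2 fold change of -0.99 ± 0.28.

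Interleukin changes were smaller. Il1b was 1.40-fold higher (0.48 ± 0.13, adjusted p = 0.037, 12 of 12 samples), Il6 at least 1.04-fold (adjusted p = 0.037, 11 of 12 samples, with 5 of 12 healthy samples above the negative controls) and the interleukin-1 antagonist Il1rn 1.36-fold (0.45 ± 0.13, adjusted p = 0.022, 11 of 12), and all 3 calls were lost under TMM scaling, DESeq2 size factors and total-count scaling. Tnf (0.17 ± 0.17, adjusted p = 0.45) and Nos2 (0.05 ± 0.26, adjusted p = 0.86) did not pass. Nos2 was near background, above the negative controls in 5 of 12 healthy and 9 of 12 untreated samples. Of the 12 IL-1, TNF and IL-6 family genes, 5 rose and 2 fell (5 and 4 when adjusted over the list alone), and the list did not pass (fry, adjusted p = 0.21). The interleukin-1 receptor genes Il1r1 and Il1rap rose by 0.60 ± 0.11 and 0.42 ± 0.08, and Ltb, which encodes a lymphotoxin, had a log2 fold change of -0.82 ± 0.12. Among 4 lymphocyte and hematopoietic cytokines, Il12a was lower (-0.51 ± 0.10), also when adjusted over the list alone, and the others did not pass (fry, downward, adjusted p = 0.64, with a median of 0.04).

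Complement genes moved both ways. Of 14, 5 rose and 4 fell (7 and 4 when adjusted over the list alone), and the list did not pass (fry, adjusted p = 0.10). Masp1, which encodes a protease of the lectin pathway and lay above the negative controls in 1 of 12 healthy and 12 of 12 untreated samples, rose at least 1.86-fold, the receptor gene C3ar1 by a log2 fold change of 1.54 ± 0.34 and C2 by 1.39 ± 0.20. Cfd, which encodes the adipocyte-derived factor D, had a log2 fold change of -1.53 ± 0.36, C7 of -1.33 ± 0.36 and C3 of -0.53 ± 0.14. Of 15 toll-like receptors and innate sensors, 4 rose (3 when adjusted over the list alone; fry, adjusted p = 0.029), among them Nod1 (0.39 ± 0.09) and Tlr5 (0.60 ± 0.14), and of 7 tissue growth factor genes 2 rose, also when adjusted over the list alone (fry, adjusted p = 0.017), namely Tgfb3 (1.33 ± 0.18) and the vascular endothelial growth factor receptor gene Flt1 (0.74 ± 0.12). The innate sensor list gave adjusted p = 0.25, 0.19 and 0.049 under TMM scaling, DESeq2 size factors and total-count scaling, which each ended the call of Nod1, and the growth factor list gave 0.20, 0.18 and 0.14. Of 19 MAP kinase and AP-1 genes, 3 rose and 4 fell, also when adjusted over the list alone (fry, adjusted p = 0.80), with Fos at 0.91 ± 0.20 and Map2k6 at -0.63 ± 0.18. This list's median log2 fold change was -0.02 and its mean 0.05. Of 12 NF-kB pathway genes edgeR called 0 over all genes and 0 when adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 1 called higher by the DESeq2 Wald test (fry, adjusted p = 0.56). For that list fry turned downward under TMM scaling (adjusted p = 4.9e-06, 4 genes lower), DESeq2 size factors (8.5e-06) and total-count scaling (0.034), and for the MAP kinase list under TMM scaling (0.0093) and DESeq2 size factors (0.010).

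Markers of other cell types were lower in loaded joints or moved both ways. Of 4 granulocyte markers, 3 fell (fry, adjusted p = 0.0050), namely Mmp9, Ccr3 and Alox15, while Cxcr2 did not pass. All 4 also stand on other lists, so these are calls already given above, and Csf3r, S100a8 and S100a9 had no probe here. Of 7 lymphocyte and antigen presentation markers, 5 fell (fry, adjusted p = 0.0031). For both lists the numbers were the same when adjusted over each list alone. Cd4 had a log2 fold change of -0.50 ± 0.16, H2-Eb1, an MHC class II gene, of -0.42 ± 0.15 and Ccr7 of -0.50 ± 0.17. Of 13 macrophage and monocyte markers, 4 rose, Arg1 among them, and 4 fell, Retnla among them (5 and 5 when adjusted over the list alone; fry, adjusted p = 0.67). Of the 3 genes of the muscle list, only Fxyd2, which encodes a sodium pump subunit and is not specific to muscle, was lower (-0.70 ± 0.32, adjusted p = 0.038, 11 of 12 samples, lost in 8 of 20 alternatives), and none passed when adjusted over the list alone. Ppp1r12b was at 0.04 ± 0.36 and Myl2 at -0.39 ± 0.70, and Myl2, the cardiac and slow-muscle myosin light chain gene, ranged from 10.7 to 788 normalized counts between healthy samples (fry, adjusted p = 0.69). The macrophage marker Mrc1, the mannose receptor gene, was lower (-0.36 ± 0.10), as was Bcl2l1 (-0.66 ± 0.10), which encodes an inhibitor of apoptosis and stands on none of these lists.

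The split of the loading calls depended on the scaling, and their number rose to 139 under array weights. TMM scaling called 98 genes, 47 higher and 51 lower, DESeq2 size factors 47 and 50, and total-count scaling 51 and 45, and TMM scaling shifted log2 fold changes by a median of -0.19 here, -0.15 in siMMP13 and -0.24 in siNEG against healthy joints. No gene was called in opposite directions by any of these scalings. The housekeeping genes themselves shifted relative to each other. Mean log2 normalized counts in healthy and untreated joints were 8.93 and 9.38 for Gusb, 7.60 and 7.29 for Hprt, and 11.24 and 11.06 for Tubb5. Cltc (11.67 and 11.70), Gapdh (12.46 and 12.46) and Pgk1 (9.39 and 9.39) differed less. Whether these shifts account for the changed split was not tested.

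**Figure D1:**
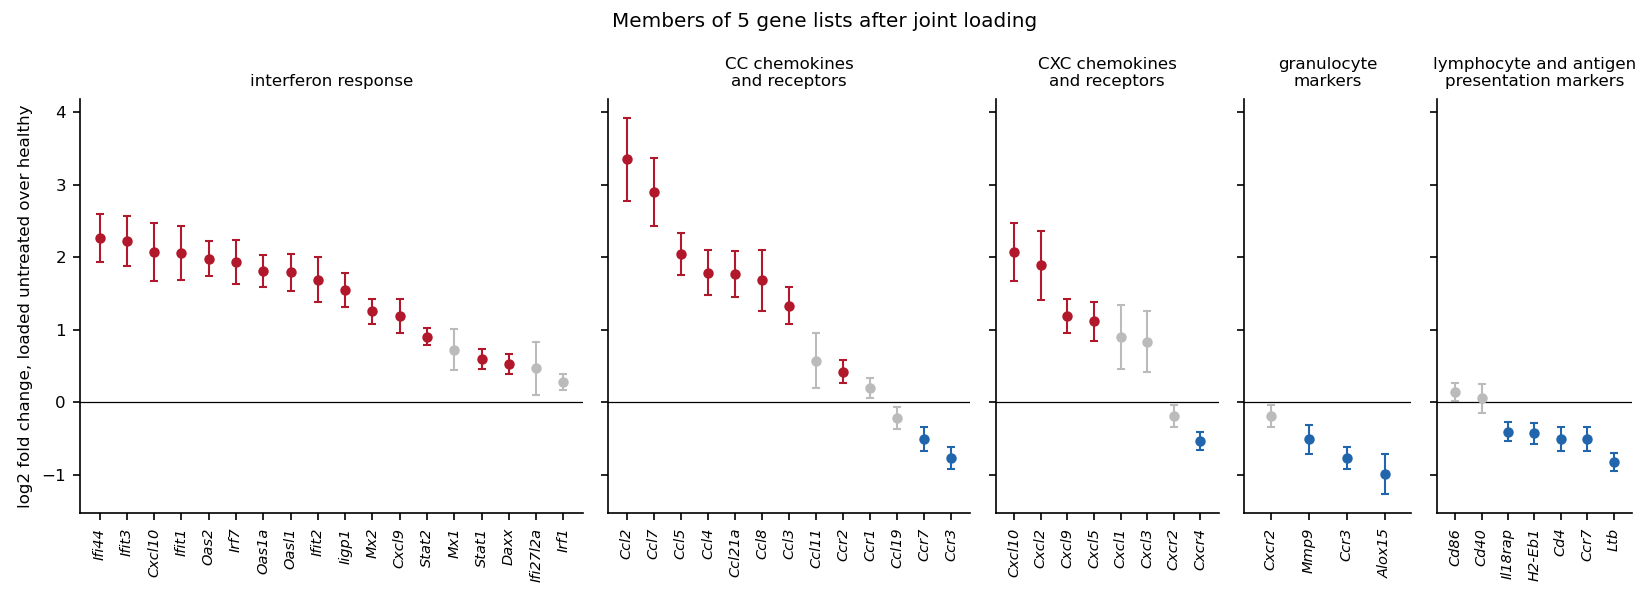
Fitted log2 fold change (y axis), also for genes near background, of loaded untreated over healthy joints for every tested member of 5 gene lists, with bars of 1 SE and n = 12 per group. Red points rose, blue points fell and grey points did not pass an adjusted p of 0.05, and 15 of 18 interferon response genes lie among the red points.

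The second comparison set siMMP13 against siNEG, which share the injury and the carrier. Tyrobp and Trem2, which encode partners in a receptor complex of myeloid cells, were higher with siMMP13. Tyrobp, the signalling adaptor, was 1.68-fold higher, at 9888 ± 4028 normalized counts (SD, n = 12) against 5879 ± 1398 (0.75 ± 0.17, adjusted p = 0.0023), above the siNEG median in 11 of 12 samples. Trem2 was 1.59-fold higher (0.67 ± 0.18, adjusted p = 0.028, 11 of 12 samples) and the interleukin-6 receptor gene Il6ra 1.41-fold higher (0.49 ± 0.17, adjusted p = 0.043, 10 of 12 samples). In all, 12 genes differed by edgeR's quasi-likelihood test, 3 higher and 9 lower, none of them by more than 2-fold.

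The 9 lower genes included Ptgfr (-0.55 ± 0.20), Flt1 (-0.43 ± 0.14), the G protein subunit gene Gnaq (-0.42 ± 0.16), Mafk (-0.33 ± 0.10) and Il1rap (-0.31 ± 0.07, adjusted p = 0.028). Smaller decreases were found for Myc (-0.28 ± 0.07), the kinase gene Mapk8 (-0.27 ± 0.07), the transcription factor gene Atf2 (-0.26 ± 0.04, adjusted p = 0.0063) and Traf2 (-0.25 ± 0.06), a signal transducer of TNF receptors. Atf2 was below the siNEG median in 12 of 12 siMMP13 samples.

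No gene list passed in this comparison. Of 13 macrophage and monocyte markers 2 rose, and 3 when adjusted over the list alone (fry, adjusted p = 0.31, and 0.0033 under TMM scaling), with Cd86, a costimulatory molecule, at 0.44 ± 0.17 (adjusted p = 0.086) and C3ar1 at 0.50 ± 0.32. Of 7 lymphocyte and antigen presentation markers none was called over all genes and 2 rose when adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 0 by the DESeq2 Wald test (fry, adjusted p = 0.25, and 0.017 under TMM scaling). Of 19 MAP kinase and AP-1 genes 2 fell, also when adjusted over the list alone (fry, adjusted p = 0.088), and of 12 oxidative and endoplasmic reticulum stress genes 1 fell, also when adjusted over the list alone (fry, adjusted p = 0.088), with Hspb1 at -1.01 ± 0.50 (adjusted p = 0.19). Of the 18 interferon response genes edgeR and the DESeq2 Wald test called 0, with 1 at an unadjusted p under 0.05 (median log2 difference 0.09 and mean 0.06, whereas fry pointed downward, adjusted p = 0.80).

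None of the 9 genes fixed in advance to be named whatever their p passed between the siRNA groups. Mmp3 was at 1726 ± 978 normalized counts with siMMP13 and 2065 ± 1102 with siNEG (SD, n = 12; -0.26 ± 0.44, adjusted p = 0.76). Mmp9 (0.05 ± 0.21), Il1b (-0.25 ± 0.22), Tnf (0.32 ± 0.19), Il6 (-0.31 ± 0.30), Nos2 (0.09 ± 0.21), Ptgs2 (-0.44 ± 0.36), Il1rn (0.28 ± 0.17) and Arg1 (-0.11 ± 0.59) had adjusted p-values from 0.29 to 0.92, and Nos2 was near background in both groups, with 6 of 12 siMMP13 and 5 of 12 siNEG samples above the negative controls.

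These 12 calls were sensitive to scaling and samples, with 2 to 13 genes called when single samples were left out. TMM scaling and DESeq2 size factors each called 9 genes, 8 higher and 1 lower, and total-count scaling called 3 higher and 11 lower. TMM scaling kept 4 of the 12, namely Tyrobp, Trem2, Il6ra and Gnaq, and total-count scaling kept 7. Without 3 siMMP13 libraries and 1 healthy library with a divergent housekeeping profile, 5 genes were called, 4 of them among the 12, with Tyrobp at 0.44 (adjusted p = 0.025) and Trem2 at 0.80 (adjusted p = 0.0062), against highest values over 20 alternatives of 0.025 and 0.067.

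**Figure D2:**
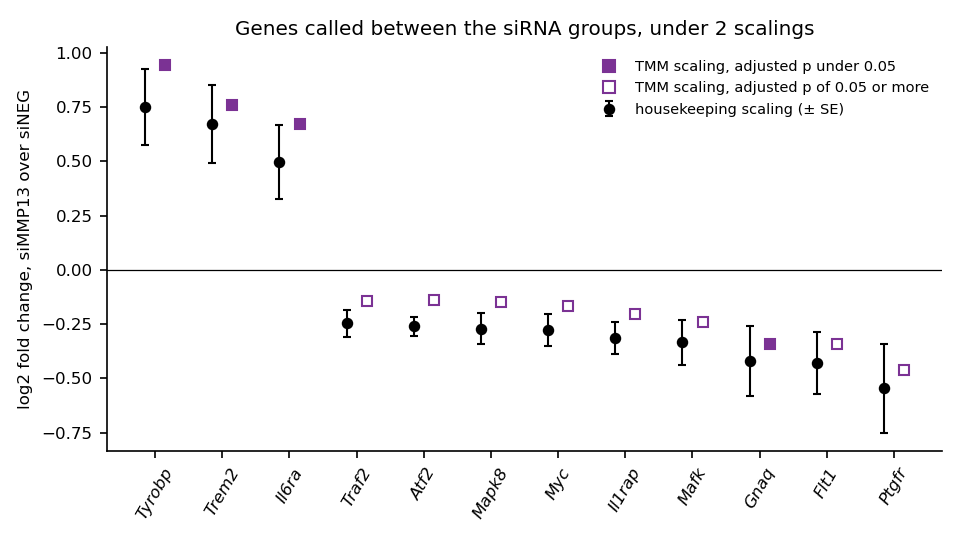
Log2 fold change of siMMP13 over siNEG (y axis) for the 12 genes called, n = 12 per group. Black circles with bars of 1 SE show the housekeeping scaling and purple squares TMM scaling, filled where the adjusted p under TMM scaling was below 0.05, which held for 4 genes.

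Whether siMMP13 moved the loading-associated genes back was tested directly. On the mean sign-weighted log2 scale over the 91 loading genes, centred on healthy joints, loaded untreated joints lay at 1.09 ± 0.27, siNEG joints at 1.08 ± 0.24 and siMMP13 joints at 0.99 ± 0.42 (SD, n = 12 each). The siMMP13 minus siNEG difference was -0.09 (95% bootstrap interval -0.36 to 0.18, two-sided permutation test, p = 0.54), so no reversal was detected, and shifts within that interval are not excluded. The 91 genes were called in the comparison of untreated with healthy samples, so the distance between those groups follows from the choice. The siRNA groups entered the filter and the spread of that fit, and over 99 genes called from the healthy and untreated samples alone the difference was also -0.09 (permutation p = 0.54). Without the 4 libraries with a divergent housekeeping profile the difference was 0.08 over the same 91 genes (permutation p = 0.50) and 0.09 over the 110 loading genes called without those libraries (p = 0.44).

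**Figure D3:**
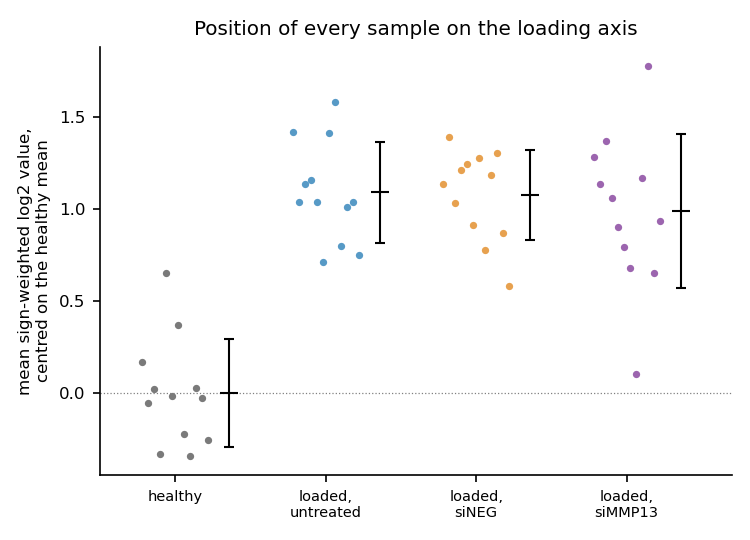
Mean sign-weighted log2 value over the 91 genes called in loaded untreated against healthy joints (y axis), centred on the healthy mean, for each sample of the 4 groups (n = 12 each), with the mean and SD in black. The 3 loaded groups have means of 1.09, 1.08 and 0.99.

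The third comparison set siMMP13 against no treatment in loaded joints, so the siRNA and its carrier differed together. Ccl19, Tyrobp, Cd86 and the MHC class II gene H2-Eb1 were higher with siMMP13. Ccl19, a chemokine that attracts dendritic cells and T cells, was 1.79-fold higher, at 208 ± 88.2 normalized counts (SD, n = 12) against 116 ± 24.4 (0.84 ± 0.17, adjusted p = 0.0037), in 12 of 12 samples above the untreated median. Ccl19 was also called higher with siNEG than without treatment (184 ± 64.0), and was not called between the siRNA groups. Tyrobp (0.63 ± 0.16), Cd86 (0.60 ± 0.16) and H2-Eb1 (0.44 ± 0.09, adjusted p = 0.027) were also higher. Il1rap (-0.36 ± 0.06) and Myc (-0.35 ± 0.09) were lower, each below the untreated median in 12 of 12 samples. In total edgeR called 7 genes, 4 higher and 3 lower. Trem2, chosen for mention here after its values were seen, did not pass against untreated joints with siMMP13 (0.29 ± 0.18, adjusted p = 0.39) or with siNEG (-0.38 ± 0.17, adjusted p = 0.57).

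By list, 2 of 13 macrophage and monocyte markers (fry, adjusted p = 0.81) and 2 of 7 lymphocyte and antigen presentation markers (fry, adjusted p = 0.41) rose, and Cd86 stands on both lists. Of 13 CC chemokines and receptors 1 rose (fry, adjusted p = 0.81), with Ccl11 at 0.65 ± 0.32 and Ccl8 at 0.57 ± 0.34. These numbers were the same when adjusted over each list alone. Of 12 IL-1, TNF and IL-6 family genes 1 fell, also when adjusted over the list alone (fry, downward, adjusted p = 0.92, with a mean of 0.02). Mmp3 (-0.03 ± 0.43), Mmp9 (0.21 ± 0.22), Il1b (0.04 ± 0.14), Tnf (0.32 ± 0.15), Il6 (0.27 ± 0.20), Nos2 (0.33 ± 0.21), Ptgs2 (-0.29 ± 0.31), Il1rn (0.21 ± 0.15) and Arg1 (0.06 ± 0.56) did not pass. Nos2 was near background, above the negative controls in 6 of 12 siMMP13 and 9 of 12 untreated samples. TMM scaling and DESeq2 size factors each called 13 genes, 9 higher and 4 lower, and total-count scaling called 2 higher and 8 lower. Without the divergent libraries the calls of Tyrobp (0.32) and Cd86 (0.37) were lost. Median Myl2 was 39.7 normalized counts in untreated, 265 in siNEG, 286 in siMMP13 and 49.2 in healthy joints. With log2 Myl2 as a covariate, added after the data were seen, 19 genes were called, and array weights called 17.

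The carrier with control siRNA was compared with no treatment. Ccl19 was higher with siNEG, at 184 ± 64.0 normalized counts (SD, n = 12) against 116 ± 24.4 (0.66 ± 0.16, adjusted p = 0.035, 11 of 12 samples). Traf2 was 1.24-fold higher (0.31 ± 0.06, adjusted p = 0.023, 12 of 12 samples), while siMMP13 against untreated joints, a value looked up after the fact, gave 0.07 ± 0.07 (adjusted p = 0.65). In total edgeR called 3 genes, 2 higher and 1 lower, none of the 17 lists passed, and 16 genes had an unadjusted p under 0.05. Under TMM scaling, DESeq2 size factors or total-count scaling edgeR called 0 genes, with 20, 21 and 20 at an unadjusted p under 0.05, while the DESeq2 Wald test under housekeeping scaling called 3.

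Both siRNA groups were also compared with healthy joints. In siMMP13 joints, Ccl2 was 11.1-fold higher (3.47 ± 0.67), Ccl7 9.29-fold (3.22 ± 0.57), Cxcl10 7.81-fold (2.96 ± 0.52), Ifit3 6.00-fold (2.58 ± 0.44) and Arg1 at least 2.85-fold. Retnla (-1.88 ± 0.53), the alternatively activated macrophage marker gene Chi3l3 (-1.06 ± 0.32), Fxyd2 (-0.97 ± 0.32), Ccr3 (-0.92 ± 0.16) and Ltb (-0.84 ± 0.17) were lower. In siNEG joints, Ccl2 was 9.16-fold higher (3.20 ± 0.56), Hspb1 8.16-fold (3.03 ± 0.39), Ccl7 7.56-fold (2.92 ± 0.48), Mmp3 5.86-fold (2.55 ± 0.56) and Ptgs2 at least 2.46-fold. Retnla (-2.28 ± 0.45), Alox15 (-0.85 ± 0.28), Ltb (-0.82 ± 0.15), the leukotriene synthesis gene Alox5 (-0.76 ± 0.16) and Chi3l3 (-0.71 ± 0.20) were lower. The siMMP13 comparison called 97 genes, 68 higher and 29 lower, and the siNEG comparison 98 genes, 74 higher and 24 lower. The muscle gene Myl2 had a median of 49.2 normalized counts in healthy joints against 286 with siMMP13 (1.68 ± 0.85, adjusted p = 0.044) and 265 with siNEG (1.31 ± 0.65, adjusted p = 0.11).

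Of 18 interferon response genes, 16 rose in each of these comparisons, and 17 with siMMP13 and 16 with siNEG when adjusted over the list alone (fry, adjusted p = 3.6e-06 and 9.7e-07). Of 13 CC chemokines and receptors 10 rose and 2 fell in each (11 and 2 with siMMP13, 10 and 2 with siNEG when adjusted over the list alone; fry, adjusted p = 3.6e-06 and 3.2e-05). Granulocyte markers fell, 2 of 4 with siMMP13 and 3 of 4 with siNEG, also when adjusted over the list alone (fry, adjusted p = 0.0040 and 0.0051). With siNEG, 6 of 14 complement genes rose, also when adjusted over the list alone (fry, adjusted p = 0.0051) and with siMMP13 6 rose and 1 fell, again also over the list alone (fry, adjusted p = 0.086). With siNEG, 5 of 7 growth factor genes rose and 1 fell (fry, adjusted p = 0.0051), 4 of 15 innate sensors rose (0.047), and 3 of 12 oxidative and endoplasmic reticulum stress genes rose and 2 fell (0.024), with 5 and 1, 3 and 0, and 3 and 2 when adjusted over each list alone. Under TMM scaling these 3 list tests did not pass (adjusted p = 0.14, 0.92 and 0.36). TMM scaling called 54 higher and 52 lower genes with siMMP13, and 51 higher and 62 lower with siNEG. DESeq2 size factors called 58 and 50, and 51 and 59, and total-count scaling 47 and 63, and 51 and 51.

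**Figure D4:**
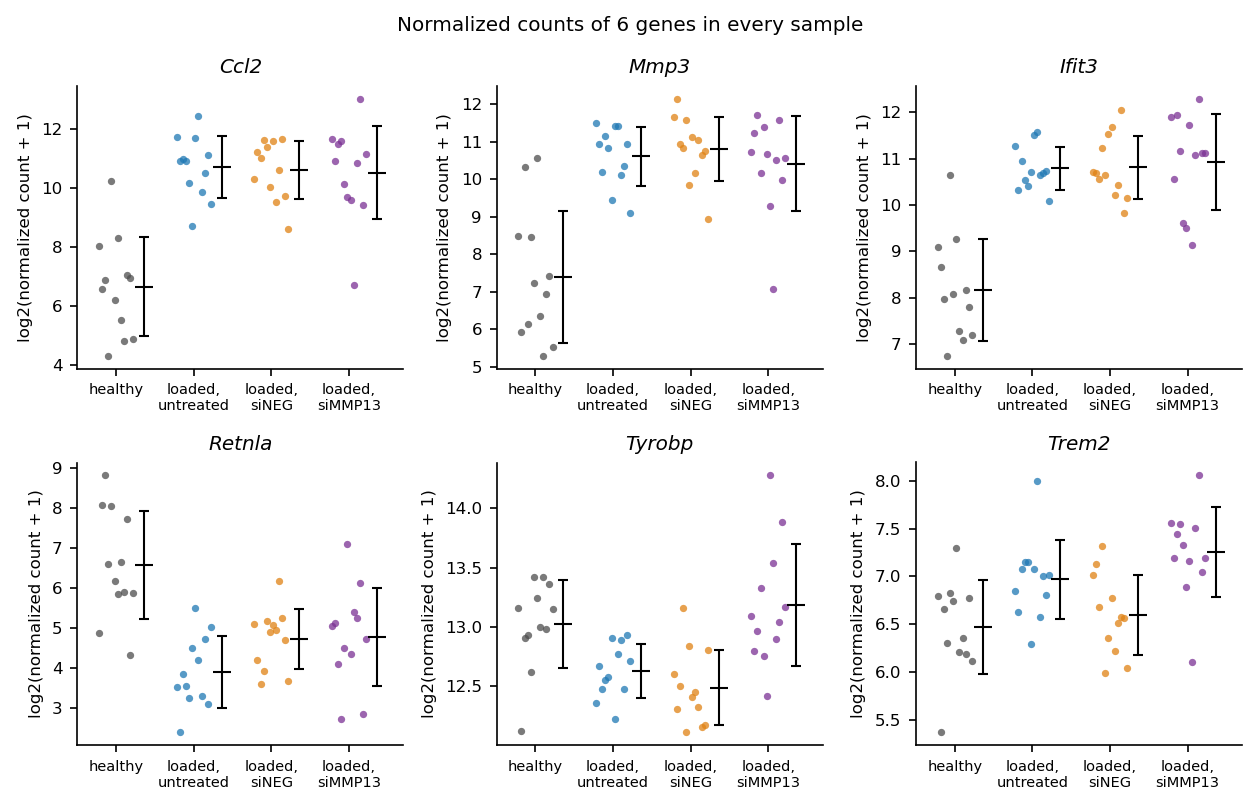
Log2(normalized count + 1) (y axis) of Ccl2, Mmp3, Ifit3, Retnla, Tyrobp and Trem2 in each sample of the 4 groups (n = 12 each), with the mean and SD in black. Ccl2, Mmp3 and Ifit3 lie higher and Retnla lower in the 3 loaded groups than in healthy joints, and Tyrobp and Trem2 lie higher with siMMP13 than with siNEG.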

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

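The test of the scaling choice and the model with Myl2 as a covariate were chosen only after results were seen, as were leaving out the libraries with a divergent housekeeping profile and leaving out sets of other libraries for comparison.

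Spiked-in positive controls, which no comparison uses, were higher in siMMP13 samples than in the control samples. Their geometric mean was 1627 ± 229 counts (SD, n = 12) with siMMP13, 1361 ± 138 in healthy joints (two-sided permutation test, adjusted p = 0.0057 over 8 comparisons) and 1181 ± 174 with siNEG (adjusted p = 0.00024), which also lay below healthy joints (adjusted p = 0.021). Negative controls averaged 8.47 ± 1.60 with siMMP13 and 5.63 ± 1.72 with siNEG (adjusted p = 0.0026), and neither passed against the 7.14 ± 1.54 of healthy joints (adjusted p = 0.069 and 0.058). A factor shared by a whole lane cancels in the housekeeping scaling, and the assignment of samples to cartridges is not given in the sources used here.

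The changes with loading were weighed first. Of 100 splits of the 24 untreated loaded and healthy samples, 1 called as many as 91 genes, the real one, and the highest of the others called 54. Chance can thus be excluded only if the samples are independent, which the labels do not state. With log2 Myl2 as a covariate 89 of the 91 calls were kept, which met the bound set for excluding muscle carried along. Median Myl2 differed little between these groups (39.7 normalized counts in untreated and 49.2 in healthy joints), so the covariate could remove few calls. The test therefore does not decide whether muscle contributed. A lower share of blood and marrow cells would raise stromal genes about as much as the genes called higher. The median log2 fold change of 9 stromal genes was 0.60 (95% bootstrap interval 0.47 to 0.72) against 1.11, which met the bound written beforehand for excluding it. However, the genes called higher were picked for rising and the stromal genes were not, so this gap does not decide the question. All 9 stromal genes had a positive log2 fold change, from 0.21 (Pdgfa) to 1.33 (Tgfb3), so such a lower share stays open. A response of the joint to loading, the difference the design names, remains a hypothesis, and a change within single cell types stays open.

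The siMMP13 against siNEG calls were weighed next. Of 100 splits of these 24 samples, 5 called as many as the real 12 genes and the highest of the others called 26, so chance cannot be excluded. Under TMM scaling 4 of the 12 calls were kept, as under DESeq2 size factors, while total-count scaling kept 7. The 8 lost under TMM scaling had the same sign with a smaller median size (0.18 on the log2 scale, median SE 0.09, against 0.30 and 0.07 before). The choice of scaling may therefore account for those 8, although not every other scaling lost as many. Without the divergent libraries 4 were also kept (median size of the 8 lost 0.25, SE 0.10, against 0.38 and 0.12), but 9 of 84 sets of 3 other siMMP13 libraries, left out with the same healthy library, kept 4 or fewer, and the median set kept 9. The bound written beforehand took such a share as excluding the divergent libraries. That was wrong because such a share only fails to single them out, so their effect and that of fewer samples cannot be told apart. An effect of the siRNA sequence stays open. So does a technical difference, because positive and negative control counts also differed between these groups and the cartridges are not given.

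Against untreated joints, 2 of 100 splits, the real one included, called as many as the 7 siMMP13 genes. That share met the bound written beforehand for excluding chance, but the highest of the others called 23. A split with several times the real count leaves chance possible for these calls. For siNEG against untreated joints 1 of 100 splits reached the real 3 genes (highest other 1). Against healthy joints it was 1 of 100 for the 97 siMMP13 genes (highest other 61) and 1 of 100 for the 98 siNEG genes (highest other 50). Positive controls stood at 1371 ± 205 counts in untreated joints (SD), against 1627 ± 229 with siMMP13 and 1181 ± 174 with siNEG, differences that were not tested. Both siRNA groups also differed from healthy joints in these controls, so a technical difference stays open for these comparisons too.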

How the results depend on the processing

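Leaving out the divergent libraries, the Myl2 covariate, and fry under total-count scaling and DESeq2 size factors were chosen after the data were seen, as were the loading scores over the same 91 genes without those libraries and over genes chosen on healthy and untreated samples alone. Apart from the tests of the lost siMMP13 against siNEG calls, causes of these changes were not tested.

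No named gene was called in the opposite direction in any alternative. Of the 20 alternatives, 44 of 57 named loading calls held in every one that tested the gene, as did 1 of 12 for siMMP13 against siNEG, 1 of 7 and 0 of 3 for siMMP13 and siNEG against untreated, and 10 of 10 and 9 of 10 against healthy joints. A gene that an alternative left untested was judged on the others. Of 3066 named-gene values without a left-out sample, 2861 kept their side of the threshold, 179 lost it and 26 gained it. Of 408 list tests 346 kept theirs, 31 gained and 10 lost it, and 21 turned. The mean loading score of each loaded group moved by less than 1 SD under TMM and total-count scaling, the only settings run for it. Positive-control scaling before the housekeeping step was not run, since its factor cancels. Counts near the filter limit what low genes can show.

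The loading count became 139 under array weights and was 79 to 96 with single samples left out. The siMMP13 against siNEG count of 12 became 3 without Gusb, 3 without Hprt, 2 without Tubb5, 4 with no filter, 4 with only the 2 groups fitted and 5 without the divergent libraries. With single samples left out it was 2 to 13: 3 without siMMP13 replicates 1, 7 or 12, 4 without 8 or 11 and 7 without 4, and for siNEG 7 without replicate 1, 4 without 5, 3 without 7, 6 without 8, 9 or 11 and 2 without 10. The siMMP13 against untreated count of 7 became 13 under TMM scaling and 13 under DESeq2 size factors, 4 without Tubb5, 17 under array weights and 19 with the Myl2 covariate (6 to 8 with single samples left out). The siNEG against untreated count of 3 became 0 in edgeR under TMM, DESeq2 size factors and total-count scaling and without Gusb or Tubb5, with 20, 21, 20, 13 and 15 genes at an unadjusted p under 0.05. It was 3 by the DESeq2 Wald test and 7 under array weights, and 1 to 4 with single samples left out (1 without siNEG replicates 4 or 6 or untreated replicates 1 or 3). Against healthy joints the ranges were 87 to 106 with siMMP13 and 91 to 104 with siNEG.

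The difference in loading score between siMMP13 and siNEG was uncalled in each alternative run on it, at -0.16 to -0.01 with single samples left out (p = 0.22 to 0.94), -0.06 as a slope over all genes, -0.09 over 99 genes chosen on healthy and untreated samples alone, -0.05 under TMM and -0.05 under total-count scaling, and -0.09 with labels permuted within replicate numbers (p = 0.41), and turned to 0.08 over the same 91 genes and 0.09 over 110 genes called anew without the divergent libraries. The other scalings, filters and tests were not run on this score.

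Correlations did not settle whether replicate numbers pair the samples. Of 12 same-numbered pairs per pair of groups, 4 to 6 correlated above 0.1. Between 0 and 4 samples of 12 correlated best with their own number, with 4 for siNEG and siMMP13. With the replicate block the counts were 89 for loading, 2 for siMMP13 against siNEG, 6 and 2 for siMMP13 and siNEG against untreated, and 97 and 96 against healthy joints. The block changed none of the 102 list calls.

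Lists whose fry direction turned are given by adjusted p. The NF-kB list turned downward against healthy joints under TMM, total-count scaling and DESeq2 size factors, at 4.9e-06, 0.034 and 8.5e-06 in untreated, 2.1e-06, 7.4e-07 and 1.7e-05 in siMMP13 and 1.2e-05, 0.017 and 7.0e-05 in siNEG joints. The MAP kinase list turned downward at 0.0093 (TMM) and 0.010 (DESeq2 size factors) in untreated joints, and at 0.00071, 0.017 and 0.0010 in siNEG joints, in the order above. In siNEG joints the oxidative stress list turned at 0.36, 0.95 and 0.66, the macrophage list at 0.0041, 0.017 and 0.012, and the innate sensor list at 0.92 under TMM.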

Other observations

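No test in this part was chosen after results were seen, and only values are given.

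Ccl2, Mmp3 and Retnla spread widely between healthy joints. Ccl2 ran from 18.8 to 1205 normalized counts over the 12 healthy samples and Mmp3 from 38.2 to 1518, while in loaded untreated joints they ran from 418 to 5603 and from 544 to 2869. Retnla ran from 19.0 to 449 in healthy and from 4.24 to 44.4 in loaded untreated joints. Tyrobp had a median of 8631 in healthy joints, 6317 in untreated, 5520 in siNEG and 8588 in siMMP13 joints, where single samples reached 19828.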
